A study of Homo sapiens with 12 samples.

How the data were processed

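CD4 and CD8 T cells had been sorted from peripheral blood mononuclear cells of patients with AML at early lymphocyte recovery. Per the labels, cells carrying the myeloid and progenitor markers CD33, CD34, CD123, CD11c or CD36 were first removed with antibodies, and CD3-positive CD4 or CD8 cells were then sorted to high purity. RNA was isolated with TRIzol, amplified with the NuGEN Ovation Pico whole-transcript kit, labelled with biotin and hybridized to Affymetrix arrays. The 12 arrays form 4 groups of 3: CD4 and CD8 cells from 3 patients given induction chemotherapy plus pomalidomide (CP, replicates 1 to 3) and from 3 given induction chemotherapy only (C, replicates 4 to 6). The labels give the CD4 and the CD8 array of a patient the same number.

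The deposited values are log2 expression values per probe set, made by the authors with RMA, which corrects the background, quantile normalizes the arrays and summarizes each probe set; no version is stated. Array medians lay between 6.38 and 6.43 in CD4 and between 5.25 and 5.32 in CD8 cells, so the arrays of each cell type had been normalized apart. A comparison of CP with C within a cell type is not touched by this, while levels in CD8 and CD4 cells are offset, and the planned comparison between cell types had assumed a common scale. It is therefore given relative to the median shift and with other scalings. The number of arrays limits the precision. An exact test of 3 arrays against 3 cannot go below a p of 0.10, so the comparisons rest on limma, which shares information about the spread over genes.

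Of the 49495 probe sets, 45284 pair with exactly 1 gene symbol, 1333 with several and 2878 with none, and the latter groups were not used here. 69 probe sets were left out to protect the patients' privacy. Of 18216 genes 11813 had several probe sets, and the one with the highest mean over the 12 arrays stood for the gene. Genes with a mean at or above the 30th percentile, 4.83 log2 units, were tested, 12751 in all. Of these 210 were tested but are not named, only in part for the same reason. The naming rule also left out T cell receptor and immunoglobulin segments and genes with only a LOC, MIR, SNOR or RNU symbol.

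One linear model with a mean for each group was fitted over all 12 arrays with limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8). The patient number was a random block (duplicateCorrelation, consensus 0.113), the variances were moderated with a trend on the mean, and p values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. All tests were two-sided. The comparisons were CP against C in CD4, in CD8, averaged over both, the difference of these differences, and CD8 against CD4. As a check of the pairing, the correlation over genes between a patient's CD4 and CD8 arrays, each relative to its group mean, was 0.084 to 0.204 for arrays with the same number and -0.195 to 0.104 for others, and each CD4 array was closest to the CD8 array with its own number.

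The 37 gene lists, the 31 key genes, the filter, the model and the rule for named genes were fixed before the data were examined. Lists were tested with limma's camera on the moderated statistics with its preset correlation of 0.01 and adjusted over the 37 lists. The test was repeated with an estimated correlation between genes and with fry, which asks whether a list's genes move one way on balance. For each list, members were also adjusted over the list alone. The lists hold 556 tested genes, of which 75 stand in several lists. Some members of the lists and some key genes are not reported here. The text names, for the comparison of CP with C in each cell type, the genes past the threshold, filled up to the 10 highest and 10 lowest moderated statistics and given as values, the key genes, and up to 4 members of each list. For the average and the difference between cell types it names the 5 genes with the lowest p, and for CD8 against CD4 the 8 called genes with the largest differences in each direction. These choices were part of the rule, while C10orf88 was named after its value was seen.

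The procedure was tested on simulated data with the same groups and 12751 genes, in which known genes differed in CD4 cells only. At adjusted p 0.05 it recovered 16.4% of genes that differed by 1 log2 unit, 65.7% of those that differed by 2 and 90.9% of those that differed by 3, with 10 false calls in CD4 and 0 in CD8 cells. camera recovered the simulated list and called 0 of 40 unchanged lists. The simulated noise was drawn independently for each gene, so genes of a list did not vary together. In the data the estimated correlation was 0.432 for the interferon and 0.735 for the monocyte list. The simulation therefore cannot show how often the preset correlation gives false list calls in these data.

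Alternatives fixed beforehand were another threshold, a minimum log2 difference of 1, leaving out each patient, other filters, quantile normalization again within each cell type and over all arrays, centring each array on its median, averaging the probe sets of a gene, fitting each cell type alone, no replicate block or a fixed one, array weights, other variance models, an equal-variance test without moderation, and the other set tests. Added after seeing the data were the mean of the monocyte genes as a covariate and leaving out the arrays highest in monocyte genes, 1 CD8 array of CP or 3 CD4 arrays. All 10 splits of the 6 patients into 3 and 3 were also fitted, as were the 32 exchanges of the CD4 and CD8 labels within patients, the latter also with each array centred on its median, which was added later. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.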

Results

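CD4 and CD8 T cells were sorted from the peripheral blood of patients with acute myeloid leukaemia (AML) at early lymphocyte recovery, the time when lymphocytes return after induction chemotherapy, and their RNA was profiled on Affymetrix expression arrays. 3 patients had received induction chemotherapy with pomalidomide (CP) and 3 had received induction chemotherapy alone (C). Pomalidomide is an immunomodulatory drug that binds cereblon, the substrate receptor of a ubiquitin ligase, and directs it to the Ikaros family transcription factors IKZF1 and IKZF3. Each of the 6 patients gave 1 CD4 and 1 CD8 array, so the series held 12 arrays in 4 groups of 3. The values were RMA log2 expression values, and 12751 of 18216 named genes were bright enough to be tested. Array medians lay between 6.38 and 6.43 in CD4 cells and between 5.25 and 5.32 in CD8 cells. The number of arrays limits the precision: the median 95% interval of a difference between CP and C in either cell type reached 0.75 log2 units to each side.

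The first comparison asked how CD4 T cells differed between patients given pomalidomide and patients given chemotherapy alone. Genes induced by type I interferon were lower in CP, 33 of the 34 tested members, with a median log2 difference of -1.08 (adjusted p = 1.4e-13, and adjusted p = 0.441 with an estimated correlation). Genes of naive and central memory T cells were higher, 20 of 23 members with a median of 0.62 (adjusted p = 9.85e-05, and adjusted p = 0.539 with an estimated correlation). Cytoplasmic ribosomal proteins were higher as well, 34 of 37 members with a median of 0.10 (adjusted p = 1.87e-08, and adjusted p = 0.441 with an estimated correlation). No single gene passed. limma called 0 of 12751 genes at adjusted p 0.05, and 628 genes had an unadjusted p under 0.05 where 638 were expected by chance. An equal-variance t test on the CD4 arrays alone, without moderation of the variances, called 0 genes, with 744 at an unadjusted p under 0.05. The 3 CP and 3 C arrays did not overlap in 11.7% of genes, against 10% expected by chance.

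The gene nearest to the threshold in CD4 cells was TAF13, a subunit of the general transcription factor TFIID, at 3.53 ± 0.19 in CP and 6.18 ± 0.49 in C (SD, n = 3 each). Its log2 difference was -2.65 ± 0.34 (SE), with an adjusted p of 0.087 in limma. The CP level lay below both the 4.83 asked of a gene's mean for testing and the lower quartile of every CD4 array (4.57 to 4.65), so the difference may not be exact. The same end of the ranking held NANP, a phosphatase of sialic acid synthesis, at -2.40, AFF3 at -1.87 and KLRK1, which encodes the activating receptor NKG2D, at -1.70, each with an adjusted p of 0.391. In CP, NANP (4.62) and KLRK1 (4.67) also lay below 4.83 and near those lower quartiles. KLRK1 was the 1 gene of the CD8 lineage list that passed when adjusted over the list alone in this comparison. ERLIN1 (-1.61), TTC9C (-2.30), the ubiquitin ligase TRIM21 (-1.51), the cathepsin inhibitor CSTB (-0.89), MOB1B (-1.22) and ZNF124 (-1.28) completed the lowest 10 statistics. At the other end stood DNAAF11 with a log2 difference of 1.46 ± 0.26 (SE) and an adjusted p of 0.391. ASB13 (0.97), ARMCX4 (1.01), the phospholipase PLA2G10 (1.33), the keratin KRT72 (2.79), MAP3K7CL (1.80), the ribosomal protein gene RPS18 (0.48), the catenin CTNND1 (1.46), SCARNA10 (0.97) and the desmosomal cadherin DSC1 (3.58) followed, with an adjusted p of 0.954. Other probe sets of MOB1B, AFF3, ASB13, MAP3K7CL and CTNND1 included at least 1 with the opposite sign.

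Of the 37 gene lists fixed beforehand, 8 passed the camera set test in CD4 cells, 5 higher and 3 lower in CP, and 0 passed with an estimated correlation between the genes of a list. In the interferon list OAS1, a sensor of double-stranded RNA, lay at -3.10, and USP18, which restrains interferon signalling, at -1.94. IRF9, part of the transcription factor complex that interferon activates, lay at -1.07 and IFI27 at -1.48. The mean of the interferon list was 8.40 ± 0.25 in CP and 9.49 ± 0.62 in C (SD, n = 3 each). The leading naive and central memory genes were NOG (1.30), FOXP1 (0.77), SATB1 (0.50) and APBA2 (1.22). The leading ribosomal protein genes were RPS16 (0.26), RPLP2 (0.35), RPL34 (0.20) and RPS27 (0.20). Members of these 8 lists past the threshold numbered 0 over all genes and 0 adjusted over the list alone.

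A further group of lists in CD4 cells passed by less. T cell transcription factors were higher, 17 of 26 members with a median of 0.24 (adjusted p = 0.0393, and adjusted p = 0.441 with an estimated correlation), with KLF3 at 0.97, FOXO1 at 0.63 and ID3, which went the other way, at -0.96. Without CP replicate 3 the median was 0.20 (adjusted p = 0.149), and without C replicate 6 it was 0.20 (adjusted p = 0.489). Of 18 alternatives with the preset correlation 11 kept this call, and it was also lost with no filter (0.24, adjusted p = 0.0555), centred arrays (0.32, 0.0521), averaged probe sets (0.25, 0.0928), the monocyte mean as a covariate (0.25, 0.114) and without the 3 CD4 arrays with the highest monocyte means (0.22, 0.0621). Oxidative phosphorylation genes were lower, 23 of 33 members with a median of -0.15 (adjusted p = 0.0144, and adjusted p = 0.579 with an estimated correlation), led by ATP5F1B at -0.34 and NDUFA8 at -1.05. Their median was -0.13 without CP replicate 1 (adjusted p = 0.102), -0.14 without CP replicate 2 (adjusted p = 0.13), -0.12 without C replicate 6 (adjusted p = 0.144) and -0.07 with each array centred on its median (adjusted p = 0.0743). It was -0.15 with a filter at the median of genes (adjusted p = 0.0779), -0.10 with averaged probe sets (0.0732) and -0.13 with array weights (0.0681), and 11 of 18 alternatives kept the call. Regulatory T cell genes were lower, 13 of 18 members with a median of -0.49 (adjusted p = 0.044, and adjusted p = 0.441 with an estimated correlation), with IL10RA at -0.49 and IKZF4 at -1.09, while FOXP3 itself stood at 0.37. Their median was -0.53 without CP replicate 2 (adjusted p = 0.146), -0.47 without CP replicate 3 (adjusted p = 0.148), -0.21 without C replicate 6 (adjusted p = 0.154) and -0.27 with probe sets averaged per gene (adjusted p = 0.0752). Only 6 of 18 alternatives kept this call. It was also lost without the 3 CD4 arrays with the highest monocyte means (-0.17, adjusted p = 0.266), without the CP CD8 array with the highest (-0.49, 0.054), with the monocyte mean as a covariate (-0.42, 0.125) and with a filter at the median of genes (-0.39, 0.379). The other losses came with quantile normalization within each cell type (-0.44, 0.0619) and over all arrays (-0.45, 0.0659), array weights (-0.44, 0.0691) and each cell type fitted alone (-0.49, 0.061). Ribosomal proteins kept their call under other scalings, but their median was 0.18 with each array centred on its median, 0.04 after quantile normalization over all arrays and 0.05 after it within each cell type, so its size depended on the scaling.

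The monocyte list was higher in CP in CD4 cells, 17 of 18 tested members with a median of 0.83 (adjusted p = 0.044, and adjusted p = 0.829 with an estimated correlation). Its mean was 7.85 ± 1.40 in CP and 6.74 ± 1.74 in C (SD, n = 3 each), with overlapping ranges of 6.31 to 9.06 and 5.64 to 8.76. LYZ, the gene of lysozyme, differed by 2.47 and FCN1 by 2.37. The median of the monocyte list was 1.49 without CP replicate 1 (adjusted p = 5.03e-06), 1.73 without C replicate 4 (adjusted p = 8.4e-07), 0.41 without CP replicate 2 (adjusted p = 0.717), 0.43 without C replicate 5 (adjusted p = 0.49) and 0.51 without C replicate 6 (adjusted p = 0.489). Of 18 alternatives 7 kept this call. It was also lost with no filter (0.76, adjusted p = 0.101), quantile normalization within each cell type (0.84, 0.0607) and over all arrays (0.83, 0.0602), centred arrays (0.91, 0.0929), averaged probe sets (0.71, 0.0732) and array weights (0.77, 0.0691). The neutrophil and granule list had only 4 tested members, all higher, with a median of 0.41 (adjusted p = 0.0427, and adjusted p = 0.441 with an estimated correlation). Its median was 0.49 without CP replicate 2 (adjusted p = 0.104), 0.34 without C replicate 4 (adjusted p = 0.169), 0.43 without C replicate 5 (adjusted p = 0.131), 0.48 without C replicate 6 (adjusted p = 0.0536) and 0.11 with no filter on the level (adjusted p = 0.13). It lost the call too with quantile normalization within each cell type (0.36, adjusted p = 0.112) and over all arrays (0.35, 0.111), averaged probe sets (0.40, 0.0752) and the monocyte mean as a covariate (0.39, 0.112), and 7 of 17 alternatives kept it. Without the 3 CD4 arrays with the highest monocyte means, 2 of CP and 1 of C, 2 of the 37 lists passed in CD4 cells. The interferon list was among them at -1.06 (adjusted p = 0.000387), while naive and central memory genes (0.46, adjusted p = 0.0667), ribosomal proteins (0.06, adjusted p = 0.0621), monocyte genes (0.41, adjusted p = 0.373) and neutrophil genes (0.29, adjusted p = 0.376) were not. In the settings that kept the preset correlation of camera the adjusted p of the interferon list ranged from 5.85e-24 to 0.000387, against an adjusted p = 0.441 with an estimated correlation and 0.411 with the set test fry. Its median was nearest to 0 without C replicate 6, at -0.68 (adjusted p = 9.33e-09).

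The second comparison put the same question to CD8 T cells. Proliferation genes were higher in CP, 23 of 25 tested members with a median log2 difference of 0.87 (adjusted p = 5.5e-06, and adjusted p = 0.499 with an estimated correlation). Among them were the cyclin CCNA2 (2.15) and PCNA (0.90), the sliding clamp of DNA replication. Glycolysis genes were higher, 14 of 20 members with a median of 0.12 (adjusted p = 0.00159, and adjusted p = 0.499 with an estimated correlation), with PGK1 at 0.90, PKM at 1.22 and GAPDH at 0.42. Interferon-induced genes were lower, 30 of 34 members with a median of -0.47 (adjusted p = 0.00826, and adjusted p = 0.687 with an estimated correlation), with USP18 at -2.12, IRF7 at -1.57, IRF9 at -1.02 and HERC5 at -1.57. The groups overlapped in the mean of this list, with the CP arrays (7.28 to 7.74) inside the range of the C arrays (6.98 to 9.07). No single gene passed here either. limma called 0 genes at adjusted p 0.05, and 1317 genes had an unadjusted p under 0.05 where 638 were expected. Other splits of the same 6 patients gave 688 to 1236 such genes, and the CD8 arrays fitted alone gave 879. An equal-variance t test on the CD8 arrays alone, without moderation of the variances, called 0 genes, with 725 at an unadjusted p under 0.05. The groups did not overlap in 11.6% of genes, against 10% by chance.

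5 genes had an adjusted p under 0.1 in CD8 cells. IFITM3, an interferon-inducible membrane protein that restricts virus entry, stood at 10.61 ± 0.09 in CP and 8.17 ± 0.22 in C (SD, n = 3 each), a log2 difference of 2.44 ± 0.34 (SE) with an adjusted p of 0.0773. PGK1, an enzyme of glycolysis, differed by 0.90 ± 0.13 (SE) with an adjusted p of 0.0773, and all 9 of its probe sets had the same sign. C10orf88B (-2.95, adjusted p = 0.0756), CSRNP2 (-2.78) and HAUS8 (-2.01), a subunit of the augmin complex of the mitotic spindle, were lower, the last pair with an adjusted p of 0.0773. In CP, C10orf88B lay at 3.56, CSRNP2 at 3.70, HAUS8 at 4.01 and USP18 at 3.56, near the lower quartiles of the CD8 arrays (3.515 to 3.59), where differences may not be exact. LYSMD1 lay below them in CP (3.27), and NRIP1 lay at 3.99 in C. C10orf88B is a near copy of C10orf88, which lay at -1.66, and C10orf88B, CSRNP2, PML, ATG9A and LYSMD1 each had at least 1 other probe set of the opposite sign. CCNA2 and GDE1 (2.05) followed with an adjusted p of 0.103. ERMN (2.77), the calcium-dependent kinase CAMK2D (1.73), GLB1L2 (1.36), the nuclear receptor corepressor NRIP1 (2.84), ACP6 (2.21) and ZNF134 (1.53) completed the highest 10 statistics, with adjusted p from 0.123 to 0.193. PML, the scaffold of nuclear bodies, was the next lowest at -1.84 (adjusted p = 0.125). INTS2 (-2.01), ARRDC1 (-1.56), NPEPL1 (-1.58), ATG9A (-1.60), LYSMD1 (-2.28) and the signalling adaptor TRAF1 (-0.90) had an adjusted p of 0.193.

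In the camera set test 5 of the 37 lists passed in CD8 cells, 4 higher and 1 lower in CP, and 0 passed with an estimated correlation. The mean of the proliferation list was 6.63 ± 0.21 in CP and 5.74 ± 0.33 in C (SD, n = 3 each). TOP2A lay at 2.84 and MKI67 at 2.48, the latter with overlapping groups and the highest of its 6 probe sets (0.31 to 2.48). Adjusted over the list alone, 2 members of the proliferation list passed, CCNA2 and PCNA, against 0 over all genes. For glycolysis 3 members passed adjusted over the list alone, GAPDH, PGK1 and PKM, and in the other lists that passed in CD8 cells 0 did. Oxidative phosphorylation genes were higher, 25 of 33 members with a median of 0.16 (adjusted p = 0.0318, and adjusted p = 0.687 with an estimated correlation), with COX4I1 at 0.47 and CYC1 at 0.76. Their median was 0.18, 0.16 and 0.11 without CP replicates 1, 2 and 3 (adjusted p = 0.0769, 0.059 and 0.199), and 0.13 and 0.08 without C replicates 4 and 5 (adjusted p = 0.0716 and 0.248). Only 6 of 18 alternatives kept this call. It was also lost with the monocyte mean as a covariate (0.14, adjusted p = 0.216), without the CP CD8 array with the highest monocyte mean (0.13, 0.169) and with a filter at the median of genes (0.16, 0.0606). The other losses came with quantile normalization within each cell type (0.12, 0.118) and over all arrays (0.12, 0.13), array weights (0.14, 0.0748) and each cell type fitted alone (0.16, 0.0633).

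Monocyte transcripts were higher in CP in CD8 cells, 18 of 18 tested members with a median of 1.84 (adjusted p = 2.27e-05, and adjusted p = 0.687 with an estimated correlation). The list mean was 7.01 ± 2.45 in CP and 5.03 ± 0.98 in C (SD, n = 3 each), and 1 CP array reached 9.70. Without that array, of CP replicate 3, the monocyte list had a median of 0.39 (adjusted p = 0.275), glycolysis genes 0.05 (adjusted p = 0.0783) and interferon genes -0.43 (adjusted p = 0.0783). Proliferation genes then lay at 0.73 (adjusted p = 0.000132) and were the 1 list that passed. In the settings that kept the preset correlation the adjusted p of the proliferation list ranged from 1.19e-09 to 0.00103, against an adjusted p = 0.499 with an estimated correlation and 0.259 with fry. Without both arrays of CP replicate 3 the monocyte list lay at 0.36 (adjusted p = 0.282) and glycolysis at 0.05 (adjusted p = 0.092). The glycolysis median was 0.25 without CP replicate 2 (adjusted p = 0.00135) and 0.22 without C replicate 4 (adjusted p = 0.00576), and with the monocyte mean as a covariate it was 0.11 (adjusted p = 0.054). The interferon list in CD8 cells lay at -0.37 without CP replicate 1 (adjusted p = 0.0911) and at -0.46 without CP replicate 3 (adjusted p = 0.0799), and at -0.90 without C replicate 4 (adjusted p = 3.13e-10). With the monocyte mean as a covariate it was -0.07 (adjusted p = 0.394). Without C replicate 6 its median was 0.10, while the test still pointed down (adjusted p = 0.854).

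**Figure D1:**
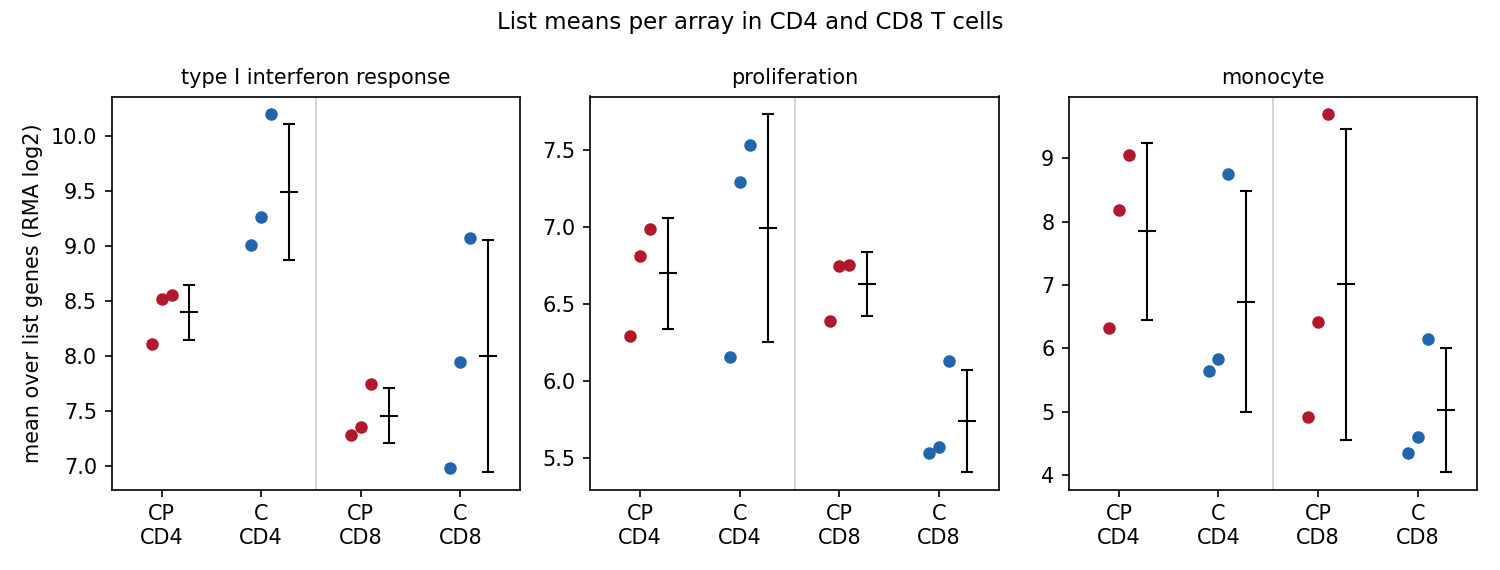
Mean RMA log2 value over the tested genes of the type I interferon, proliferation and monocyte lists in each array (dots, red for CP and blue for C, placed side by side in order of value), with the group mean and SD (black, n = 3). The y axis is in log2 units and differs between panels. In CD4 cells the 3 CP arrays lay between 8.11 and 8.56 for interferon genes and the 3 C arrays between 9.01 and 10.19, and in CD8 cells the CP arrays lay between 6.39 and 6.75 for proliferation genes and the C arrays between 5.53 and 6.13. CP and C overlapped in the rest, including interferon genes in CD8 cells (CP 7.28 to 7.74, C 6.98 to 9.07).

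The genes closest to the drug's known mechanism were compared next. CRBN, the gene of cereblon, stood at 10.56 ± 0.21 in CP and 10.78 ± 0.31 in C CD4 cells, and at 8.88 ± 0.59 and 8.88 ± 0.38 in CD8 cells (SD, n = 3 each). The 95% intervals of the difference ran from -0.90 to 0.47 in CD4 cells and from -0.68 to 0.69 in CD8 cells. IKZF1, which encodes Ikaros, differed by 0.21 in CD4 cells (adjusted p = 0.954) and by 0.36 in CD8 cells (adjusted p = 0.368). IKZF3 (0.75 and 0.01), IKZF2 (-0.39 and 0.72), IRF4 (-0.04 and 0.66) and MYC (-0.03 and -0.30) did not pass in CD4 or CD8 cells. These are RNA levels, while the drug acts on the IKZF1 and IKZF3 proteins, which were not measured. They therefore do not show whether the drug reached its targets. Among effector molecules, IFNG differed by -1.33 in CD4 cells and 0.53 in CD8 cells, TNF by -0.54 and 1.78, GZMB by -0.34 and 0.50, GZMK by -0.33 and 0.41, PRF1 by -0.19 and -0.36, and GNLY by -0.52 and 0.73. The naive markers CCR7 and LEF1 differed by 0.62 and 0.27 in CD4 cells and by -0.41 and -0.14 in CD8 cells, and IL7R, the interleukin 7 receptor, by -0.04 and -0.51. Inhibitory receptors in CD8 cells included HAVCR2 at 1.83, LAG3 at 1.52, CTLA4 at 0.80 and TIGIT at -0.58, against 0.01, 0.50, 0.83 and -0.91 in CD4 cells. FOXP3 stood at 0.37 in CD4 and -0.46 in CD8 cells. The activation markers CD38, CD69 and HLA-DRA differed by 1.81, 0.62 and 2.42 in CD8 cells and by 0.12, -0.48 and 0.97 in CD4 cells, and MKI67 by 2.48 and -0.63. Monocytes express HLA-DRA and HAVCR2 too, and the monocyte list was higher in CP CD8 cells (median 1.84), so these values cannot be assigned to T cells. The list was not higher in every CP array: replicate 1 (4.912) lay below C replicate 4 (6.154), and replicate 3 reached 9.697. Without the CD8 array of CP replicate 3 the list median was 0.39. In CD8 cells HLA-DRA did not overlap between CP and C, and its source was not tested. MKI67 did overlap there, at 8.72 ± 0.96 in CP and 6.24 ± 1.71 in C (SD, n = 3 each). The CD8 values given for both genes are the highest of their probe sets, which ran from 0.31 to 2.48 for MKI67 and from 0.37 to 2.42 for HLA-DRA. CD4 (-0.04 and -0.14), CD8A (0.34 and -0.12) and CD8B (0.41 and -0.06) did not pass in either cell type, although for CD8B in CD4 cells the CP and C arrays did not overlap. Of the 27 key genes tested, 0 passed over all genes in either cell type. Adjusted over the list alone 0 passed as well, with a smallest adjusted p of 0.806 in CD4 cells and 0.107 in CD8 cells. Other probe sets lay on the other side of 0 for IKZF1, IL7R, CTLA4, CD69, HLA-DRA, MKI67 and CD4 in CD4 cells. They did so for CRBN (-0.95 to 0.39), IKZF1 (-0.17 to 0.36), IKZF3, HAVCR2 (-0.61 to 2.74), CD69, CD4 and CD8A in CD8 cells. IL2 was below the level needed for testing.

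**Figure D2:**
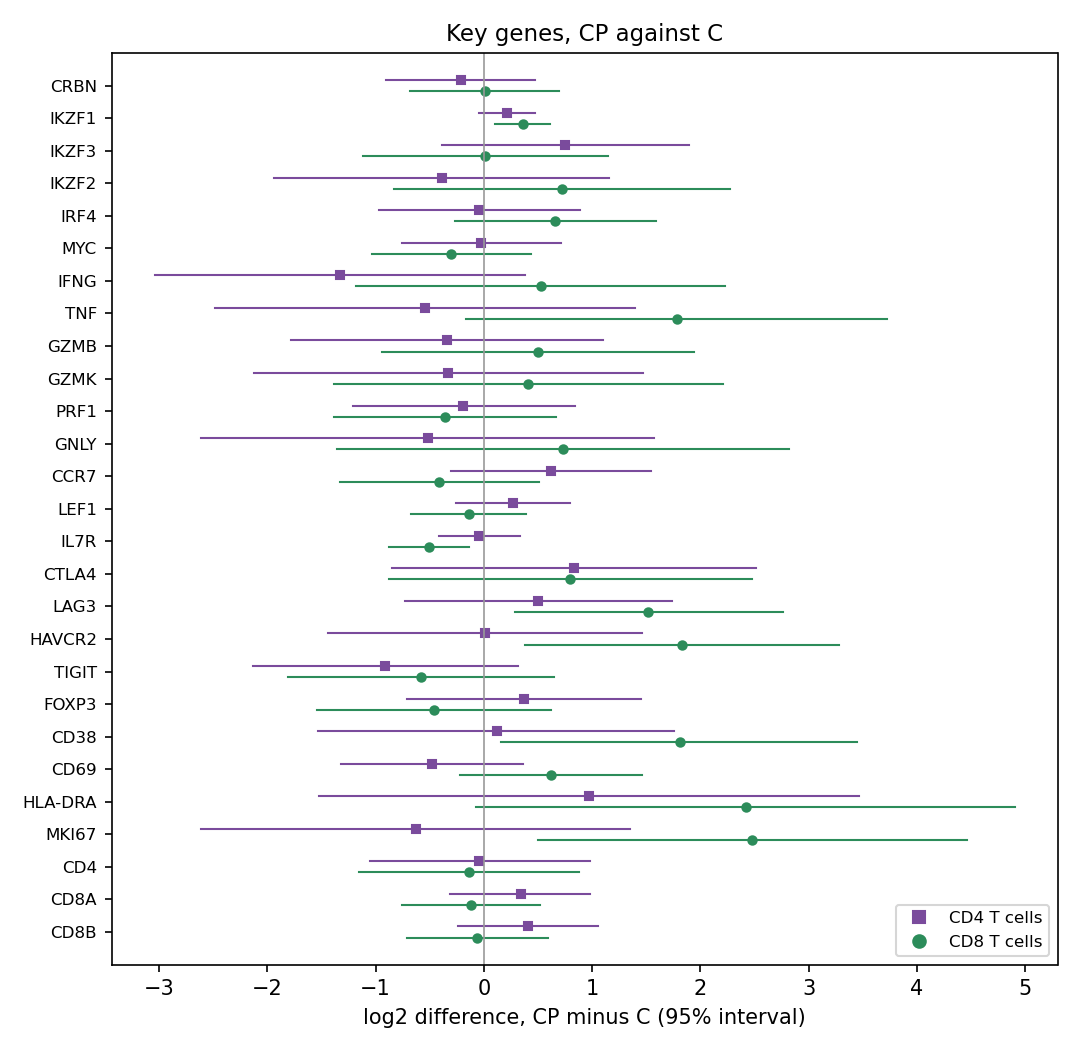
Log2 difference between CP and C for the 27 key genes tested (x axis, log2 units), with the limma 95% interval, in CD4 cells (squares) and CD8 cells (circles), each from 3 CP and 3 C arrays. The intervals of CRBN include 0 in both cell types, and the largest CD8 estimates are those of MKI67 (2.48) and HLA-DRA (2.42), the latter a gene that monocytes express too. Both are the highest of the gene's probe sets, which ran from 0.31 for MKI67 and from 0.37 for HLA-DRA.

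The remaining T cell lists did not pass in either cell type. The cereblon ligase complex had a median difference of -0.21 in CD4 (adjusted p = 0.0609) and 0.08 in CD8 cells (adjusted p = 0.478), with COPS5 at -0.72 in CD4. The reported neosubstrates of immunomodulatory drugs, again measured as RNA and not as protein, had medians of 0.07 (adjusted p = 0.842) and -0.13 (adjusted p = 0.853). Effector and cytotoxic genes had medians of -0.34 (adjusted p = 0.15) and -0.12 (adjusted p = 0.83), with GZMA at -0.96 in CD4. Inhibitory receptor and exhaustion genes lay at 0.04 (adjusted p = 0.822) and 0.21 (adjusted p = 0.484), activation and costimulation genes at 0.01 (adjusted p = 0.795) and 0.25 (adjusted p = 0.124), and cytokines at 0.06 (adjusted p = 0.795) and -0.11 (adjusted p = 0.441). Among helper subsets, Th1 genes lay at -0.41 and 0.30 (adjusted p = 0.672 and 0.462), Th2 genes at -0.32 and -0.25 (0.672 and 0.467), Th17 genes at -0.22 and 0.12 (0.868 and 0.484) and T follicular helper genes at 0.04 and 0.20 (0.868 and 0.353). Innate-like T cell genes lay at -0.06 and 0.24 (0.289 and 0.176), and chemokine receptors and homing molecules at -0.15 and -0.14 (0.795 and 0.876). For signalling, the T cell receptor list lay at -0.07 and -0.03 (0.289 and 0.853), cytokine signalling at -0.06 and -0.20 (0.559 and 0.117), NF-kB targets at 0.06 and 0.37 (0.793 and 0.353), p53 response genes at 0.30 and 0.10 (0.489 and 0.853), apoptosis regulators at -0.01 and 0.18 (0.795 and 0.81) and cholesterol synthesis at -0.21 and 0.15 (0.286 and 0.467). Immediate early and handling genes, which respond to cell isolation, lay at -0.04 and -0.07 (0.559 and 0.853). Adjusted over the list alone, LTA passed in CD8 cells in the cytokine and NF-kB lists (-1.10), TRAF1 in the NF-kB list, LGALS3 in the regulatory T cell list (2.36) and POU2AF1 in the T follicular helper list (2.74, against a C level of 3.61 near the lower quartiles).

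Lists of other lineages were read for cells that the sort could have carried along. B cell and plasma cell genes lay at 0.20 in CD4 and -0.12 in CD8 cells (adjusted p = 0.142 and 0.853), natural killer cell genes at 0.13 and 0.34 (0.762 and 0.353), with KLRC1 passing adjusted over the list alone in CD8 cells (2.33). Erythroid genes lay at 0.12 and -0.02 (0.795 and 0.83), and platelet genes at 0.22 and 0.15 (0.286 and 0.353), with PPBP at 1.99 and 2.75, the former against a C level of 3.78, below the lower quartile of every CD4 array, so that it may not be exact. Progenitor and blast genes lay at 0.17 and 0.16 (0.076 and 0.442), dendritic cell genes at -0.11 and 0.43 (0.868 and 0.452), the CD4 lineage list at 0.17 and 0.31 (0.692 and 0.853) and the CD8 lineage list at -0.06 and -0.10 (0.706 and 0.484). In CD8 cells the neutrophil and granule list lay at 0.39 (adjusted p = 0.117), naive and central memory genes at 0.12 (0.853), ribosomal proteins at 0.03 (0.353), T cell transcription factors at 0.01 (0.353) and regulatory T cell genes at -0.25 (0.853). In CD4 cells proliferation genes lay at -0.21 (adjusted p = 0.138) and glycolysis at -0.16 (0.0878). The median, the mean and the test differed in sign for the neosubstrate, activation, cytokine, Th17, innate-like and dendritic cell lists in CD4 cells. In CD8 cells they did so for the neosubstrate, cytokine, regulatory T cell, immediate early, T cell receptor, B cell and erythroid lists.

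**Figure D3:**
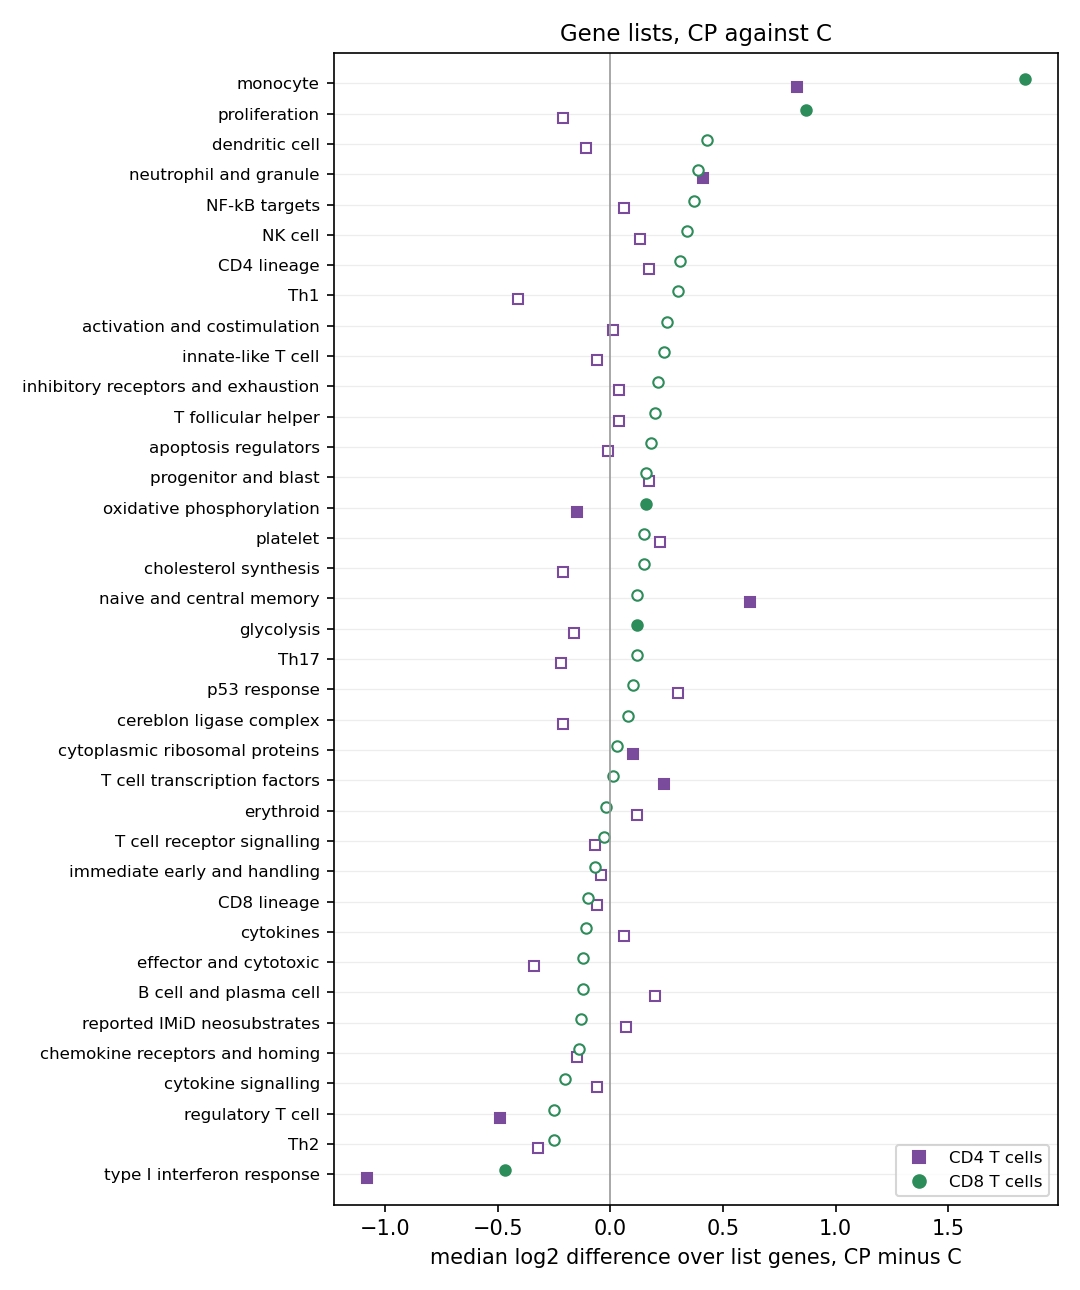
Median log2 difference between CP and C over the tested genes of each of the 37 lists (x axis, log2 units), in CD4 cells (squares) and CD8 cells (circles). Filled symbols mark lists past adjusted p 0.05 in camera with its preset correlation, 8 in CD4 and 5 in CD8 cells, and open symbols the rest.

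A further comparison averaged the difference between CP and C over both cell types. Interferon genes were lower in CP, 33 of 34 members with a median of -0.69 (adjusted p = 3.03e-11, and adjusted p = 0.666 with an estimated correlation), and IRF9, OAS1 and USP18 passed adjusted over the list alone. Without C replicate 4 the median was -1.21 (adjusted p = 6.83e-25) and without C replicate 6 it was -0.27 (adjusted p = 0.00151). Monocyte genes (1.46, 18 of 18 members, adjusted p = 5.08e-06) and ribosomal proteins (0.06, 35 of 37 members, adjusted p = 1.63e-05) were higher. Both had an adjusted p = 0.666 with an estimated correlation. In all 7 lists passed. The others were neutrophil genes (0.37, 4 of 4 members, adjusted p = 0.00893, and adjusted p = 0.534 with an estimated correlation; 0.14 with no filter, adjusted p = 0.0297), naive and central memory genes (0.26, 18 of 23, adjusted p = 0.0218), T cell transcription factors (0.25, 17 of 26, adjusted p = 0.0351) and proliferation genes (0.23, 21 of 25, adjusted p = 0.043). The last 3 had an adjusted p = 0.666 with an estimated correlation. Naive and central memory genes lost the call without CP replicates 1 and 3 and C replicate 6, at medians of 0.30, 0.21 and 0.15 (adjusted p = 0.128, 0.15 and 0.52), while the median was 0.40 without C replicate 4 (0.0207) and 0.44 without C replicate 5 (0.00043). T cell transcription factors did so without CP replicates 1 and 3 and C replicates 5 and 6, at 0.11, 0.27, 0.22 and 0.16 (0.0727, 0.15, 0.073 and 0.167). Proliferation genes did so without CP replicate 3 and C replicates 4 and 5, at 0.16, 0.30 and 0.03 (0.323, 0.0582 and 0.704), and neutrophil genes without C replicate 4, at 0.32 (0.0552). The proliferation median was 0.35 without CP replicate 1 (0.04) and C replicate 6 (0.00101). It was 0.36 with array weights (0.0272) and with a filter at the median of genes (0.0196), and 0.35 with averaged probe sets (0.00349) and without the 3 CD4 arrays with the highest monocyte means (0.0205). The monocyte median was 0.73 without CP replicate 3 (adjusted p = 0.0232) and 0.85 without its CD8 array alone (0.00965). With the monocyte mean as a covariate naive and central memory genes (0.20, adjusted p = 0.38), T cell transcription factors (0.23, 0.196), proliferation genes (0.25, 0.196) and neutrophil genes (0.30, 0.0752) lost the call. Without the CP CD8 array with the highest monocyte mean the first 3 did (0.25, 0.27 and 0.26, adjusted p = 0.306, 0.0721 and 0.0889). Without the 3 CD4 arrays with the highest, naive and central memory genes (0.23, adjusted p = 0.128) and neutrophil genes (0.31, 0.125) did. T cell transcription factors also lost it with centred arrays (0.31, 0.0536) and averaged probe sets (0.21, 0.0521), and proliferation genes with no filter (0.23, 0.0791), quantile normalization over all arrays (0.25, 0.0544) and centred arrays (0.29, 0.0921). The ribosomal median ranged with the scaling from 0.03 (0.0487 over all arrays and 0.0493 within each cell type) to 0.13 (8.74e-11, centred arrays), and was 0.10 with averaged probe sets (2.26e-05). limma called 0 genes in the average, with 976 at an unadjusted p under 0.05. An equal-variance t test on the mean of each patient's arrays, without moderation of the variances, called 0, with 652. IFITM3 (1.47) and SPCS2 (1.56) were at the upper end of the ranking and CSRNP2 (-1.66), ACTR3C (-1.56) and USP18 (-2.03) at the lower, each with an adjusted p of 0.539.

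The next comparison tested whether the difference between CP and C itself differed between the cell types. For proliferation genes the difference in CD8 minus that in CD4 cells had a median of 0.85, with 23 of 25 members above 0 (adjusted p = 5.34e-07, and adjusted p = 0.633 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.36, 28 of 33 members above 0 (adjusted p = 9.37e-05, and adjusted p = 0.633 with an estimated correlation). Glycolysis genes had a median of 0.33, 15 of 20 members above 0 (adjusted p = 6.35e-05, and adjusted p = 0.315 with an estimated correlation). Ribosomal proteins had a median of -0.07, 28 of 37 members below 0 (adjusted p = 0.0483, and adjusted p = 0.912 with an estimated correlation), and lost the call without CP replicate 2 (-0.05, adjusted p = 0.58), C replicate 4 (0.00, 0.815) and C replicate 6 (-0.07, 0.0671). They lost it too with quantile normalization within each cell type (-0.06, 0.11) and over all arrays (-0.05, 0.0968), averaged probe sets (-0.08, 0.0975) and without the 3 CD4 arrays with the highest monocyte means (-0.05, 0.407). The proliferation median was 1.30 without CP replicate 1 (adjusted p = 8.63e-08) and 1.51 without C replicate 5 (adjusted p = 6.58e-12), and that of glycolysis was 0.19 without CP replicate 3 (adjusted p = 0.0284). Adjusted over the list alone, CCNA2 and PCNA passed in the proliferation list and GAPDH, PGK1 and PKM in the glycolysis list. Without the 3 CD4 arrays with the highest monocyte means, the proliferation list lay at 0.92 (adjusted p = 0.0515) and glycolysis at 0.34 (adjusted p = 0.141). limma called 0 single genes, with 901 at an unadjusted p under 0.05. An equal-variance t test on each patient's CD8 minus CD4 difference, without moderation of the variances, called 0, with 801. TAF13 came nearest, at 3.55 ± 0.45 (SE) with an adjusted p of 0.0822, from the same low CP level in CD4 cells, followed by C10orf88B (-3.49, adjusted p = 0.117), PGK1 (1.16, adjusted p = 0.174), PCNA (1.70) and TMEM135 (3.26), the last pair with an adjusted p of 0.328. Across the 12751 genes, which are not independent replicates, the differences in CD4 and CD8 cells had a Pearson correlation of 0.162. Both came from the same patients, so chance differences between patients are part of it.

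A last comparison set CD8 against CD4 cells within patients. CD4 fell by 7.26 log2 units from CD4 to CD8 cells (10.76 ± 0.24 in CD4 and 3.50 ± 0.71 in CD8 arrays, SD, n = 6 each). That CD8 level lay below the lower quartile of every CD8 array, so the size may not be exact. CD8A was higher by 6.45 and CD8B by 4.41, as were the NK-type receptor genes KLRK1 (6.64), KLRD1 (5.82), KLRC3 (5.08) and KLRC4 (4.96) and the histone genes H2AC16 (4.46) and H2AC13 (4.42). TSHZ2 (-5.73), KANK1 (-5.00), DACT1 (-4.88), ANKRD55 (-4.85), TRIM2 (-4.85), WASH7P (-4.67) and AGO3 (-4.65) were the lowest besides CD4. The CD4 and CD8 arrays had been normalized apart, so that the median difference over all genes was -1.125 log2 units, and levels can be compared only relative to that shift. Relative to it, CD4 differed by -6.14, CD8A by 7.57, CD8B by 5.53, CD3D by -0.04, CD3G by -0.22 and CD3E by 0.92. The CD3 genes thus did not all align after the shift, and small differences between the cell types cannot be read. limma called 10147 of 12751 genes, 565 of them higher in CD8 cells. With all arrays quantile normalized together it called 5961, of which 2920 were higher, and with each array centred on its median it called 5769, of which 3166 were higher.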

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

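The fits without single patients and the splits of the patients were planned, but the use of the former to weigh these patterns, the covariate, and the covariate test and splits of the interferon list in CD8 cells were chosen after results were seen.

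The differences between CP and C were not the same in CD4 and CD8 cells for 4 gene lists, by the test of the difference between the cell types. Proliferation genes had a median of 0.85 (CD8 minus CD4, 23 of 25 members above 0), oxidative phosphorylation 0.36, glycolysis 0.33 and ribosomal proteins -0.07, with adjusted p from 0.315 to 0.912 with an estimated correlation, where none of the 4 passed. Without the 3 CD4 arrays highest in monocyte genes proliferation (0.92, adjusted p = 0.0515), glycolysis (0.34, adjusted p = 0.141) and ribosomal proteins (-0.05, adjusted p = 0.407) did not pass, and ribosomal proteins did not without CP replicate 2 (-0.05, adjusted p = 0.58), C replicate 4 (0.00, 0.815) or C replicate 6 (-0.07, 0.0671) either.

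The first pattern weighed is the higher expression of proliferation genes in CP CD8 cells (median 0.87), which did not pass with an estimated correlation (adjusted p = 0.499) or fry (0.259). A single patient as the whole source is argued against: without any one patient the median stayed at 0.64 or above and past the threshold. Monocyte transcripts as the whole source are argued against too, since with the monocyte mean as a covariate the median was 0.59 (adjusted p = 0.000185, in a range of 1.19e-09 to 0.00103 over the settings with the preset correlation). Among the 10 splits of the 6 patients, 1, the real one, moved the list this much, and the highest other gave 0.49, but 10 splits are too few for a share under 0.05. The list had also already passed with the real groups, so its rank there is not independent support. Of all 37 lists, 3 had fully separate CP and C list means in CD8 cells, where chance gives 3.7. A difference between the patients apart from the drug and an effect of pomalidomide both stay open as hypotheses.

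The second pattern is the lower expression of interferon genes in CP, which in CD4 cells did not pass with an estimated correlation (adjusted p = 0.441) or fry (0.411). In CD4 cells the median of -1.08 stayed at -0.68 or below without any one patient and was -0.85 with the monocyte mean as a covariate (adjusted p = 1.87e-09, in a range of 5.85e-24 to 0.000387 over the settings with the preset correlation), which argues against either as the whole source. The real split was again the 1 of 10 with the largest median, the highest other being 0.69 in size, and 10 splits are too few to go further. This list too had already passed with the real groups, so its rank is not independent support. Of all 37 lists, 5 had fully separate CP and C list means in CD4 cells, where chance gives 3.7. In CD8 cells 1 patient may carry the difference, since the median of -0.47 was 0.10 without C replicate 6. With the monocyte covariate it was -0.07 (adjusted p = 0.394). C replicate 6 had the lowest monocyte mean (4.347) and the highest interferon mean (9.073) of the CD8 arrays. The covariate therefore cannot be told apart from this patient. Without the CP CD8 array with the highest monocyte mean the median was still -0.43 (adjusted p = 0.0783), and without CP replicate 3 it was -0.46 (0.0799). Of the 10 splits, 7 moved the list as much, the highest other by 0.94. Other sources of interferon were not tested, and neither was an effect of the drug apart from the patients.

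For single genes the 10 splits of the 6 patients are too few for a share under 0.05. The real split gave 0 genes in CD4, CD8, the average and the difference between cell types, a count that all 10 splits reached, and the highest of the others were 1, 5, 3 and 1. For lists, the real split gave 8 in CD4, where 3 of the 10 splits gave as many and the highest other gave 9. In CD8 it gave 5, where 6 of the 10 gave as many and the highest other gave 8. The correlation of the differences in CD4 and CD8 cells was 0.162, and 5 of the 10 splits gave as much, with 0.294 as the highest other. For CD8 against CD4, 1 of the 32 exchanges of labels within patients, the real one, gave 10147 genes and the highest other gave 0. The real labels are also the sets that were normalized apart. With each array centred on its median the real one gave 5769 and the highest other 1. Centring takes only a constant from each array, and other offsets left by the separate normalization would follow the real labels too. The exchanges therefore cannot tell a difference between the cell types from the separate normalization.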

How the results depend on the processing

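The covariate and the runs without arrays high in monocyte genes were chosen after the data were seen. For genes named in CP against C, 1949 of 1960 values kept their side of the threshold and 11 gained a call, while the values of 29 of the 94 gene results spanned 0, none of them called. For lists, 161 of 233 kept both, 70 lost the call and 2 turned: the monocyte list with its own mean as covariate lay at -0.09 in CD4 and -0.14 in CD8 cells, which the covariate's construction gives. These 233 leave out the estimated correlation and fry, with which all 13 lists of CD4 and CD8 lost the call. The CD8 interferon median of 0.10 without replicate 6 counts as lost, as the test still pointed down.

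At adjusted p 0.1 the counts of genes were 1 in CD4, 5 in CD8 and 1 for the interaction. With no filter they were 1 in CD8 and 1 for the interaction, and with a filter at the median of genes 1 in CD4 and 1 for the interaction, with 5 lists in CD4. Probe sets averaged per gene gave 2 genes in CD4, 1 for the interaction and 4 lists in CD4. Centring on the median gave 1 gene in CD8, 5 lists in CD4 and 5769 genes for CD8 against CD4. Quantile normalization within each cell type gave 5 lists in CD4, and over all arrays 5 lists and 5961 genes for CD8 against CD4. Each cell type fitted alone gave 1 gene in CD4, and array weights 1 gene and 5 lists in CD4. The monocyte covariate left 4 lists in CD4 and 1 in CD8. Without the CP CD8 array highest in monocyte genes 1 list in CD8 passed and the correlation of the differences was 0.103. Without the 3 CD4 arrays highest in them, which left 1 CP CD4 array that is assumed to vary like the other groups, 2 lists in CD4 passed. An estimated correlation and fry, which tests for a shared direction, gave 0 lists in CD4 and 0 in CD8. fry also has a form that counts changes in either direction and so says nothing on direction. Its adjusted p in CD8 was 0.000785 for glycolysis and 0.0138 for proliferation, NF-kB targets and cytokines. It was 0.0145 for oxidative phosphorylation and T follicular helper genes, and the lowest in CD4 was 0.18. For the interaction it was 0.0272 for proliferation and 0.0074 for glycolysis.

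Without single patients the counts ranged from 0 to 2 genes in CD4 (2 without replicate 2, 1 without replicate 6) and from 0 to 12 in CD8 (12 without replicate 2, 6 without replicate 6, 2 without replicate 4). They ranged from 0 to 4 in the average (4 without replicate 2) and from 0 to 5 for the interaction (5 without replicate 6). Lists ranged from 3 (without replicate 6) to 10 in CD4, with 5 without replicate 2, and from 1 (without replicate 3) to 8 (without replicate 2) in CD8, with 3 without replicate 1. The correlation ranged from 0.0448 to 0.306, and the count for CD8 against CD4 from 9669 to 9802. Except where stated, the cause was not tested.

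Without the replicate block 0 genes passed in each comparison of CP with C and 9962 for CD8 against CD4, with 8 lists in CD4 and 5 in CD8. As a fixed block the pairing gave 0 genes for the interaction and 10113 for CD8 against CD4. The block changed none of these counts past adjusted p 0.05 for CP against C.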

Other observations

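The tests on monocyte transcripts were chosen after the result was seen.

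4 genes picked after the values were seen had higher means in CP than in C CD8 cells, of which only LAG3 had groups that did not overlap, while TIGIT lay at -0.58, also without overlap, and neither they nor the inhibitory receptor and activation lists passed (adjusted p = 0.484 and 0.124). TNFRSF9, the costimulatory receptor 4-1BB, differed by 1.85 (adjusted p = 0.411), beside HAVCR2 at 1.83 (adjusted p = 0.402), LAG3 at 1.52 (adjusted p = 0.411) and CD38 at 1.81 (adjusted p = 0.456). In CD4 cells the innate-like genes CXCR6 and ZBTB16, the latter a reported target of the drug class, lay at 2.00 and 1.41 (adjusted p = 0.954 each). IFITM3, which interferon induces but which was not in the interferon list, stood at 2.44 in CD8 and 0.51 in CD4 cells, opposite in sign to the list.

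The third pattern weighed is the monocyte transcripts in the sorted T cells, whose list mean ranged from 5.64 to 9.06 over the CD4 arrays and from 4.35 to 9.70 over the CD8 arrays. LYZ ranged from 5.58 to 12.32 in CD4 and from 3.10 to 11.42 in CD8 arrays, and S100A8 from 3.50 to 12.25 and from 2.77 to 11.56. Monocytes or their RNA among the sorted cells may be a source, although the removal of CD33, CD11c and CD36 cells and the CD3 sort should exclude them: the median correlation between the 18 tested members over 6 arrays was 0.903 in CD4 and 0.788 in CD8 cells, and the highest of 200 random lists gave 0.242 and 0.182. The random genes were not matched on level or spread, and any genes regulated together could exceed them. The comparison therefore does not point to monocytes in particular. Of the 18 members 2, FCER1G and TYROBP, stand in another list, and 13 in CD4 and 4 in CD8 cells were above 4.83 log2 units even in the array lowest for the list. These counts cannot be compared between the cell types, which were normalized apart (array medians 6.38 to 6.43 in CD4 and 5.25 to 5.32 in CD8). Whether the same patients are high in both sorts is open, with Spearman's rho of 0.771 and Pearson's r of 0.657 over 6 patients (exact permutation p = 0.103 and 0.0903, adjusted p = 0.103 each over both, r = 0.688 without the 2 farthest patients), and the difference in list means between CP and C did not pass (exact permutation p = 0.4 in CD4 and 0.2 in CD8, smallest possible 0.1).

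The 3 CP and 3 C arrays were fully apart in their list means for 5 of 37 lists in CD4 and 3 in CD8 cells, where chance gives 3.7.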
